A study of Mus musculus with 2 samples.

How the data were processed

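Liver RNA was sequenced from female NOG-TKm30 mice, immunodeficient NOG mice carrying a herpes simplex virus thymidine kinase mutant (clone 30) under the mouse transthyretin enhancer and promoter. The mice were 16 weeks old, and the treated group received ortho-toluidine (OTD), an aromatic amine, at 0.6% for 1 week and then 0.3% for 3 weeks. The vehicle and route of the percentages are not given in the sources used here. RNA of 3 control mice was mixed into 1 library and RNA of 5 OTD mice into another, per the labels' design text, so each group had 1 library. Per the labels' protocols, libraries were made from 200 ng of total RNA after ribosomal RNA depletion, with a directional (strand-keeping) MGI kit. The treatment protocol in the labels names C57BL mice, whereas the strain label, the titles and the design text name NOG-TKm30. The column names carry the word Wild, which the labels do not explain, and the columns were matched to the groups by the words for control and OTD.

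The deposited table gave 1 normalized expression signal per gene symbol and library, a signal the authors derived from read counts. Per the submitters' processing notes, Trimmomatic 0.38, Bowtie2, RSEM, edgeR and the mm10 build were used, with no role or order stated. The annotation release, the filter on genes and the use of strand in counting are not given in the sources used here. In each column 100% of the values were whole multiples of the value of 1 read, within a tolerance of 1e-06, so whole reads were recovered. They came to 13569189 reads in the control library and 14685193 in the OTD library. The columns behaved as CPM (reads scaled to a common total) divided by a scaling factor of 0.981 for control and 1.02 for OTD, with a product of 1. Levels below are these scaled CPM. Of 15348 listed genes, 281 in control and 215 in OTD stood at 0, and a count of 3 reads corresponded to a level of 0.225 in control and 0.200 in OTD.

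From the levels a log2 ratio of OTD over control was computed with a pseudocount of 1, which understates differences of low genes. Genes with a mean of the 2 libraries of at least 10 were called measured (7602 genes), and a gene was counted as higher or lower at an absolute log2 ratio of at least 1. With 1 library per group there was no residual degree of freedom. No test that covers variation between pools could therefore be run on the recovered reads, and no p-value is given. Ratios of levels were computed without a pseudocount and carry 95% exact Clopper-Pearson intervals on the split of reads. These intervals cover counting error only, not the variation between mice, pools or library preparations.

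The 40 gene lists (pathways, gene families and cell type markers), the rules of size and the rule for named genes were fixed before the data were examined. For each list with at least 5 measured members, the median log2 ratio was placed among the medians of 10000 random lists of the same size, matched on mean level in 20 bins. A list was said to stand apart below the percentile 2.5 or above 97.5, which describes these 2 libraries and is not a test. The named genes were the 12 highest and 12 lowest log2 ratios among genes with a mean of at least 100 (without unnamed models, small RNAs and antisense genes), 20 single genes, and for each list up to 4 members with the largest absolute log2 ratio plus the most abundant. Some genes that this rule takes are not reported here. Genes named outside this rule were chosen after their values were seen, and are named as such where they appear.

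Gene coordinates, types, lengths and GC content came from GENCODE M21 on GRCm38 (the mm10 assembly), which matched 14706 of the symbols (95.8%). Length and GC content were those of the longest annotated transcript of a gene. Sharing of sequence between gene copies was measured as the share of a gene's 50-base stretches found in transcripts of other copies. The members of the Cyp2b, Cyp2c, Cyp4a, Gstm, Mup, Hba and Hbb families resemble each other, so reads can be split between copies and the ratio of a single member is less certain than its counting interval. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9 were used. The method was tested on reads simulated for the OTD and control pools over 7614 genes. The 2-fold rule counted 66 of 67 genes changed 2.5-fold, 66 of 66 changed 4-fold and 0 of 67 changed 1.5-fold, and 0 of 7414 unchanged genes. The intervals held the true fold for 95.5% of genes. The simulated reads held counting error only, so these figures do not cover variation between mice, pools or library preparations. For the lists, values drawn independently for each gene were used in place of reads, and 6 of 100 unchanged lists of 20 genes stood apart. Lists whose genes vary together were not simulated.

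Alternatives fixed in advance were pseudocounts of 0.5 and 10, scaling to the same total, to a median log2 ratio of 0 or to the same upper quartile, a mean of at least 50 or no filter, 1.5-fold and 3-fold rules, a counting interval beyond 1.5-fold, and random lists not matched on level. A mean of at least 1, scaling without the ribosomal RNA precursor Rn45s, and removal of a trend on transcript length, GC content and abundance (cubic terms, least squares) were added after seeing the data.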

Results

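The series compared liver RNA of NOG-TKm30 mice given OTD for 4 weeks with that of untreated mice. The control library (a pool of 3 mice) held 13569189 reads and the OTD library (a pool of 5 mice) 14685193 reads over 15348 genes. Albumin (Alb) took 8.01% of the control reads and 7.10% of the OTD reads, and the 10 most abundant genes 19.7% and 19.1%. The ribosomal RNA precursor Rn45s, named after its values were seen, took 1.47% and 2.66%. Log2 levels had a Pearson r of 0.988 across genes, which are not independent replicates. Neither group had replicates, so the spread between pools was not measured and no difference below has a replicate check.

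The cytochrome P450 genes Cyp2b10 and Cyp2c29, glutathione S-transferase genes and fatty acid and cholesterol synthesis genes were higher in the OTD pool by list median or size, and PPAR-alpha targets and most major urinary protein genes were lower. Cyp2b10, the classic target of the nuclear receptor CAR, was 5.29-fold higher (95% counting interval 4.90 to 5.71), with levels of 57.5 in control and 303.8 in OTD. Cyp2c29 was 2.97-fold higher (2.92 to 3.02), from 1357 to 4033, and the glutathione S-transferase gene Gstm3 was 4.03-fold higher (3.68 to 4.41), from 43.0 to 173.3. The PPAR-alpha target Cyp4a14 was 4.97-fold lower (4.74 to 5.22), from 701.2 to 141.0, and Cyp4a10 was 2.67-fold lower (2.59 to 2.74), from 1191 to 446.6. In GRCm38, Cyp2b10 lies on chromosome 7 at 25897620 to 25926624, Cyp2c29 on chromosome 19 at 39269405 to 39330713 and Gstm3 on chromosome 3 at 107963696 to 107969283. Cyp4a14 lies on chromosome 4 at 115486200 to 115496142 and Cyp4a10 beside it at 115518264 to 115533649, and all 5 are protein-coding genes.

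Of 7602 measured genes, 16 were at least 2-fold higher and 16 at least 2-fold lower in the OTD pool. The median log2 ratio was −0.0063 (SD across genes 0.24), and 97.6% of genes lay within 1.5-fold. Among abundant genes, the 12 highest ratios also took in the lipogenic enzymes Acly (2.32-fold) and Fasn (2.21-fold), Igfbp1 (2.12-fold), Ces1g (148.7 in control, 296.9 in OTD), Aldh1a7 (1.91-fold), Gstm1 (1.81-fold), Cyp2a5 (1.81-fold), the water channel Aqp8 (1.77-fold) and the alpha-globin gene Hba-a2 (1.76-fold). The 12 lowest also took in A1bg (2.57-fold lower), Mup17 (2.47-fold lower), Mup1 (2.32-fold lower), Mup10 (2.11-fold lower), Mup9 (2.03-fold lower), Acot1 (166.9 in control, 83.4 in OTD), Arrdc3 (1.89-fold lower), Retsat (1.86-fold lower), Mup2 (1.76-fold lower) and Herpud1 (1.65-fold lower). The remaining genes past 2-fold at a mean under 100 and named by the lists were Mup19, Elovl6, Thrsp and Abcc4 among the higher, and Nr1d1, Il1r1, Vnn1, Pex11a and Axin2 among the lower. Ddit4, Ppp1r3g, Ly6a, Ikbke, Lrtm1 and 0610010B08Rik (higher) and G0s2, Plin5, Plin4 and Tsku (lower) completed the count and were named after their values were seen.

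**Figure D1:**
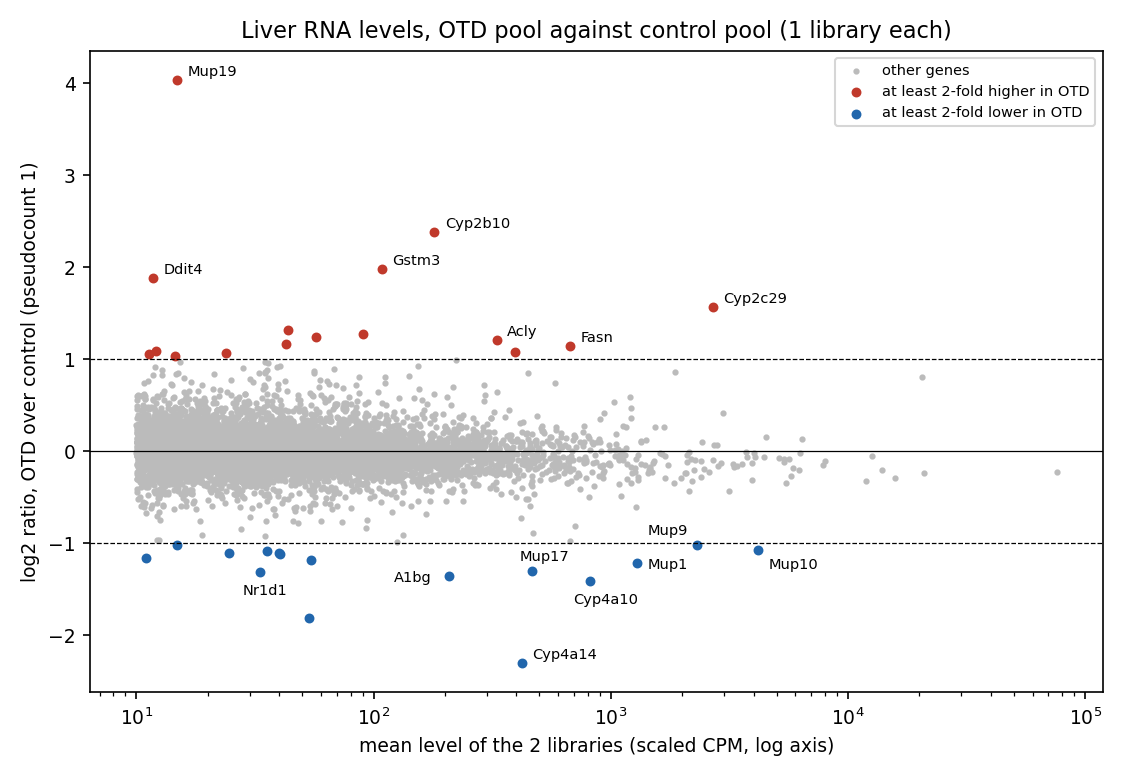
Log2 ratio of OTD over control (vertical axis, pseudocount 1) against the mean level of the 2 libraries (horizontal axis, scaled CPM, log axis) for 7602 measured genes, 1 point per gene, with dashed lines at 2-fold. The 16 genes at least 2-fold higher are red and the 16 at least 2-fold lower are blue, with Cyp2b10 at 2.38 and Cyp4a14 at −2.31.

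The gene lists asked whether genes of a pathway or cell type shifted together. Of 35 lists with a median, 8 stood apart as higher and 4 as lower in the OTD pool, where 1.75 would be outside by chance if lists were independent, which overlapping lists are not. The 1.75 also takes the genes of a list to vary independently between pools, which 1 library per group cannot check. Targets of CAR and PXR, receptors that induce drug-metabolizing enzymes, had a median log2 ratio of 0.23 over 25 members (2 at least 2-fold higher). Members differed, with 17 above 0 and 8 below, and 23 of the 25 were also on another list. Cyp2c54 was 1.67-fold higher and Cyp2a5 1.81-fold higher, while the abundant Cyp3a11 was 1.11-fold higher (1.10 to 1.13). Among the 8 members below 0, Alas1 was 1.19-fold lower (1.13 to 1.26). Further below 0 were Cyp3a44, with a ratio of 0.674 (0.631 to 0.720), and Por, with 0.722 (0.698 to 0.747). Both were named after their values were seen. The P450 genes of families 1 to 4 stood apart with a median of 0.016 over 46 members, 2 of them at least 2-fold higher and 2 at least 2-fold lower, with 25 above 0 and 21 below, and its median ranged from 0.00048 to 0.088 across the alternatives. Targets of AhR had a median of 0.14 over 7 members (percentile 97.7; 0.22 at a mean of at least 50, 0.21 after scaling to the same total without Rn45s), with Ugdh 1.68-fold higher. Of those 7 members, 6 were also on another list, as were 25 of the 46 P450 genes. Cyp1a2 was 1.17-fold higher (1.13 to 1.21), and Cyp1a1, the most inducible AhR target, stood at 0.60 in control and 0.73 in OTD (8 and 11 reads), a ratio of 1.22 with an interval of 0.448 to 3.50. The AhR and P450 lists no longer stood apart without a filter on low levels or against unmatched random lists.

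NRF2 targets, which include antioxidant and conjugating enzymes, had a median log2 ratio of 0.35, with 25 of 26 members above 0 and Gstm3 and Abcc4 at least 2-fold higher. Of those 26 members, 14 were also on another list. Ces1g had a log2 ratio of 0.99, Gsta2 was 1.99-fold higher (1.74 to 2.29), Hmox1 was 1.22-fold higher (1.07 to 1.39), and Nqo1, at a mean of 8.21, had a ratio of 1.30 (0.995 to 1.71). The glutathione S-transferase family had a median of 0.29 over 18 members, 14 of them above 0, and 8 of the 18 were also on another list. Gstm1, its most abundant member, was 1.81-fold higher (1.78 to 1.85), with levels of 1321 in control and 2397 in OTD.

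Cholesterol synthesis genes had the highest list median, 0.58, with 20 of 21 members above 0 and 0 past 2-fold. Lss was 1.88-fold higher (1.65 to 2.15), Msmo1 1.77-fold higher and Idi1 1.73-fold higher. Fatty acid synthesis genes had a median of 0.40, with 15 of 18 members above 0. Elovl6 (2.45-fold), Thrsp (2.42-fold), Acly (2.32-fold) and Fasn (2.21-fold) were at least 2-fold higher. Scd1, the most abundant member of the list, had a ratio of 0.968 (0.962 to 0.974).

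PPAR-alpha targets, which include fatty acid oxidation enzymes, had a median log2 ratio of −0.41, and all 27 measured members were below 0, 4 of them at least 2-fold lower. Beyond Cyp4a14 and Cyp4a10, Vnn1 was 2.23-fold lower (1.90 to 2.63) and Pex11a 2.16-fold lower (1.89 to 2.47). The major urinary protein genes had a median of −0.58, with 9 of 10 members below 0 and 4 at least 2-fold lower, and a mean of −0.24. At a mean of at least 50 the median was −1.05 over 6 members. Mup10 was 2.11-fold lower (2.08 to 2.13), from 5658 to 2685, while Mup19 stood at 0.83 in control and 29.0 in OTD, and all of its 50-base stretches occur in other Mup transcripts. The summed level of the 17 numbered Mup genes was 0.517 times that of control.

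**Figure D2:**
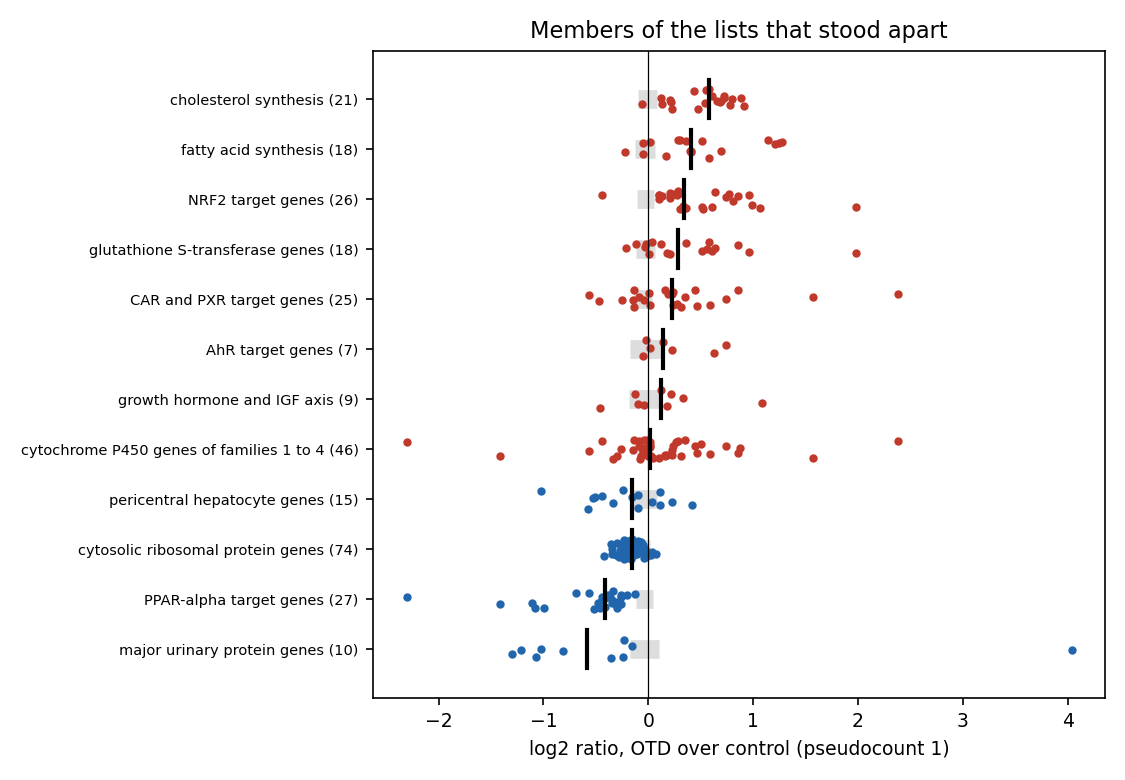
Log2 ratio of OTD over control (horizontal axis, pseudocount 1) of each measured member (points) of the 12 lists that stood apart, with the number of members in parentheses, the median as a black bar and the central 95% of medians of matched random lists in grey. All 27 PPAR-alpha targets lie below 0, and 20 of 21 cholesterol synthesis genes lie above it.

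Ribosomal protein genes were lower by a small amount, with a median log2 ratio of −0.16 and 71 of 74 members below 0, and with a median of −0.10 after scaling to the same total and −0.086 when Rn45s was also left out (61 of 74 below 0). Rps2, the most abundant, was 1.16-fold lower (1.13 to 1.20), and Rps14 1.34-fold lower (1.27 to 1.42). The growth hormone and IGF axis list had a median of 0.12 over 9 members, with Igfbp1 2.12-fold higher (2.04 to 2.21) and Igfbp2 1.38-fold lower (1.33 to 1.44). Its median was −0.040 at a mean of at least 50, and it did not stand apart there, without a filter (0.041), at a mean of at least 1 (0.041) or against unmatched random lists. Female-biased genes (median −0.038) and male-biased genes (0.12) did not stand apart, the latter except at a mean of at least 50 (0.35 over 6 members), with a pseudocount of 10 (0.12) or after trend removal (0.19), and members of both went both ways. Among female-biased genes A1bg was 2.57-fold lower (2.42 to 2.72), while Prom1 was 1.86-fold and Nipal1 1.75-fold higher. Among male-biased genes Cyp2d9 was 1.85-fold higher (1.67 to 2.06) and Mup20 1.29-fold lower.

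Of the cell type lists, pericentral hepatocyte genes alone stood apart under the rule fixed in advance. They had a median log2 ratio of −0.15 over 15 members (percentile 2.13), and did not stand apart at a mean of at least 50, where the median was −0.10, and the median was −0.098 after scaling to the same total and −0.081 when Rn45s was also left out. Of the 15 pericentral members, 10 were below 0 and 5 above, with log2 ratios up to 0.42. The Wnt target Axin2 was 2.14-fold lower (1.74 to 2.64), Tbx3 had levels of 78.9 in control and 52.5 in OTD, and Cyp2e1 was 1.27-fold lower (1.25 to 1.28). The other cell type lists had medians of −0.12 for hepatocyte core genes, −0.050 for periportal, −0.12 for Kupffer cell, −0.062 for sinusoidal endothelial, −0.045 for stellate cell, 0.012 for cholangiocyte and 0.077 for erythroid genes. The hepatocyte core median turned to 0.0084 after trend removal. All 10 measured Kupffer cell markers were below 0 (percentile 3.36), but 8 of 10 after scaling without Rn45s and 13 of 17 without a filter. Cd163 was 1.14-fold lower and Cd5l 1.11-fold lower. Alb was 1.17-fold lower and the nuclear receptor gene Hnf4a 1.42-fold lower (1.38 to 1.45). Ttr, whose promoter drives the transgene, had a ratio of 0.961 (0.950 to 0.972), and its log2 ratio of −0.058 turned positive after scaling without Rn45s. Col1a1 had a ratio of 1.17 (0.903 to 1.51), Hba-a1 of 1.07 (1.02 to 1.13) and Hba-a2 of 1.76 (1.64 to 1.90), and the cholangiocyte marker Prom1 of 1.86 (1.49 to 2.33).

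Stress, DNA damage and proliferation lists did not stand apart at a mean of at least 10 or were too low to compute. Medians were 0.040 for p53 targets, 0.056 for endoplasmic reticulum and integrated stress genes, 0.018 for interferon response genes, −0.062 for acute phase genes and −0.034 for immediate early and heat shock genes. The acute phase median turned to 0.011 after scaling without Rn45s and 0.047 after trend removal. Without a filter on low levels, p53 targets stood apart with a median of 0.24 over 20 members (percentile 99.99), and interferon response genes with 0.18 (percentile 97.95). At a mean of at least 1, p53 targets still stood apart (0.24 over 19 members), but interferon response genes did not (0.15, percentile 93.48). At a mean of at least 50, endoplasmic reticulum and integrated stress genes stood apart with 0.093 over 12 members. The p53 target Cdkn1a was 1.35-fold lower (1.25 to 1.46), while Mdm2 was 1.39-fold higher (1.20 to 1.60) and Ccng1 1.28-fold higher (1.17 to 1.40). The low-level p53 target Bbc3, which encodes the pro-apoptotic protein PUMA and was named after its value was seen, was 2.12-fold higher (1.51 to 3.01), from 50 to 119 reads. The acute phase gene Saa1 was 1.41-fold higher (1.20 to 1.65), and the metallothionein gene Mt1 had a ratio of 1.04 (0.952 to 1.13). Of 34 cell cycle genes, 4 were measured, and Mki67 stood at 3.53 in control and 3.07 in OTD (ratio 0.870, 0.567 to 1.34). At a mean of at least 1 the cell cycle list stood apart as lower, with a median of −0.15 over 17 members (percentile 1.66), but not without a filter (−0.083 over 34). Of the 13 oncofetal and preneoplastic genes listed, 2 were measured, Abcc4, 2.16-fold higher (1.83 to 2.56), and Prom1, 1.86-fold higher (1.49 to 2.33), and Afp stood at 0.30 and 0.47. Both measured genes were also on another list. Without a filter the oncofetal list did not stand apart, with a median of 0.042 over 13 genes, 6 of them below 0. The monocyte and neutrophil list had 1 measured member, Lyz2 (ratio 1.12). The lymphoid list had 0, and only 2 of its 17 genes were among the deposited genes. Of the 13 mitochondrially encoded genes, 0 were among the deposited genes under the symbols used, so their levels are not known here.

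The heme, iron and bile acid lists did not stand apart, with medians of 0.0071, −0.12 and −0.0088. Hamp, which encodes the iron hormone hepcidin, was 1.28-fold lower (1.24 to 1.31), and Alas1, the first enzyme of heme synthesis, 1.19-fold lower (1.13 to 1.26). Cyp7a1, the rate-limiting enzyme of bile acid synthesis, was 1.11-fold lower (1.04 to 1.19). The clock list had a median of −0.084, with Nr1d1 2.57-fold lower (2.23 to 2.98), and gluconeogenesis and amino acid catabolism of −0.00075. Medians were 0.054 for UDP-glucuronosyltransferase, −0.16 for sulfotransferase, 0.058 for arylamine N-acetyltransferase and deacetylase, and −0.10 for histone genes, and these lists did not stand apart either. Without a filter the histone list (−0.11 over 69 members) and the clock list (−0.11 over 18) stood apart as lower, but the clock list had −0.0027 over 15 members at a mean of at least 1 and did not. Against unmatched random lists the iron (−0.12), hepatocyte core (−0.12) and sulfotransferase (−0.16) lists did too, and after trend removal UDP-glucuronosyltransferase genes stood apart as higher (0.15). Nat2, the arylamine N-acetyltransferase gene, had a ratio of 1.05 (0.823 to 1.33), a difference not detectable at this depth.

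**Figure D3:**
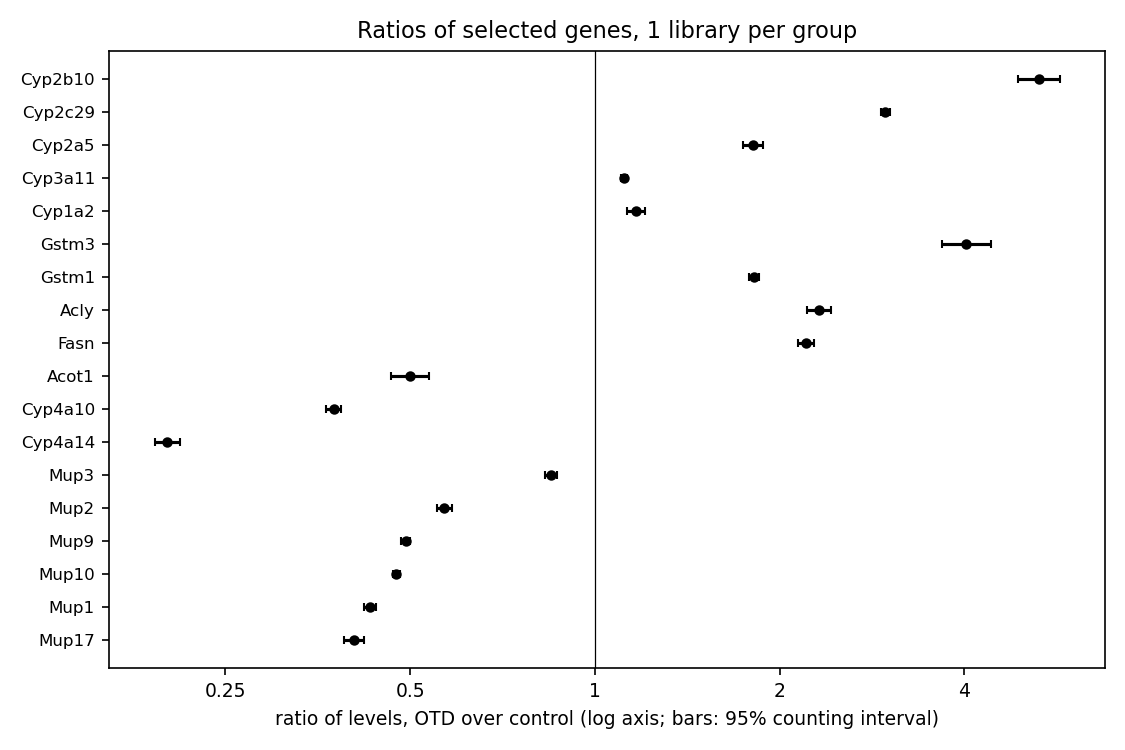
Ratio of OTD over control levels (horizontal axis, log axis, no pseudocount) for selected P450, glutathione S-transferase, lipogenic, PPAR-alpha target and Mup genes, 1 library per group, with bars for the 95% counting interval, which covers counting error only. Cyp2b10 lies at 5.29 and Cyp4a14 at 0.201, and 5 of the 6 Mup genes drawn lie under 0.6, with Mup3, chosen after its value was seen, at 0.848.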

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

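Of 377 list medians computed under the alternatives, 352 kept their side of the rule, and 8 of the 12 lists that stood apart did so under each alternative. These were the CAR and PXR, PPAR-alpha, NRF2, cholesterol synthesis, fatty acid synthesis, glutathione S-transferase, Mup and ribosomal protein lists. The median of the PPAR-alpha list ranged from −0.43 to −0.34 and that of cholesterol synthesis from 0.51 to 0.65, while that of the Mup list ranged more widely, from −1.05 (6 members at a mean of at least 50) to −0.51, and that of ribosomal proteins from −0.17 to −0.086 (scaling without Rn45s). The other 4 depended on the filter or on the random lists, and the cause was not tested. At a mean of at least 50 the growth hormone list turned to −0.040, the pericentral list weakened to −0.10 and the P450 list to 0.0064. Without a filter the AhR list had 0.12, the growth hormone list 0.041 and the P450 list 0.017, and at a mean of at least 1 (added after seeing the data) the growth hormone list had 0.041 and the P450 list 0.016, none past the rule. Against unmatched random lists AhR (0.14), growth hormone (0.12) and P450 (0.016) did not stand apart. The counts of 16 higher and 16 lower genes became 8 and 9 at a mean of at least 50, 44 and 26 without a filter and 39 and 25 at a mean of at least 1, as fewer or more genes entered. They became 115 and 69 at 1.5-fold and 4 and 2 at 3-fold, where the size threshold itself differed. A pseudocount of 10 gave 10 lower and also fewer than 16 higher. All 16 and 16 also had a counting interval beyond 1.5-fold. At the read numbers of measured genes a 2-fold ratio nearly fixes that outcome, so it adds little. Scaling to the same total gave 20 higher and 14 lower. Of 23 lists that did not stand apart, the median of 16 had either sign under some setting, and 14 values passed the rule, among them p53 targets without a filter (0.24). Of 1296 values of named genes, 187 moved beyond the counting interval and 0 past 2-fold changed sign. No paired analysis was possible because each group had 1 library, which also ruled out leaving a library out.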

Other observations

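Genes named in this paragraph, other than Id1 and Smad7, were chosen after their values were seen. As a group these genes form no list fixed in advance, and no group of them was tested. Some are single members of lists described above: Plin2 (PPAR-alpha), Cyp2c55 (CAR and PXR), Sqle (cholesterol synthesis), Oasl1 (interferon response) and Krt19 (cholangiocyte). In the OTD pool G0s2, an inhibitor of the lipase ATGL, was 3.61-fold lower (3.20 to 4.08), Plin4 2.44-fold lower (1.90 to 3.14) and Plin5 2.31-fold lower (2.07 to 2.57), while Plin2 was 1.30-fold lower (1.26 to 1.35). The keratin genes Krt8 and Krt18 were 1.61-fold (1.51 to 1.71) and 1.57-fold (1.46 to 1.69) higher, Krt19 had a ratio of 1.27 (0.703 to 2.33), and the tight junction gene Cldn1 was 1.44-fold higher (1.34 to 1.55). Ikbke was 2.28-fold higher (1.80 to 2.91), and at low levels Tlr3 was 2.43-fold higher (1.68 to 3.56) and Oasl1 2.24-fold higher (1.69 to 2.99). Id1 was 2.07-fold (1.65 to 2.61), Id3 1.56-fold (1.36 to 1.79) and Smad7 1.47-fold lower (1.29 to 1.67), and the iron list that holds Id1 and Smad7 did not stand apart. Also at low level, Cyp2c55 had 11 reads in control and 113 in OTD (9.13-fold, 4.92 to 18.8), and Sqle was 3.56-fold higher (2.32 to 5.64). On chromosome 2, the zinc-finger genes Gm14308 and Gm4724 had 158 and 139 reads in control and 2 each in OTD, and 93.9% of the 50-base stretches of Gm4724 occur in Gm14308.

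The tests below were chosen after the patterns were seen, except the comparison of ribosomal protein genes with other genes of like length, whose bounds were written before its result was seen. Genes in these tests that the rule for named genes does not take were also chosen after the values were seen. In the OTD pool PPAR-alpha targets were lower and CAR and PXR, NRF2, cholesterol and fatty acid synthesis genes were higher. A trend on annotated length, GC content and abundance is argued against as the cause, since 5 of the 5 lists still stood apart the same way once it was removed. The trend accounted for 2.23% of the variance of the log2 ratios. Removing so weak a trend could change little, and the random lists were already matched on mean level. A more fed state of the OTD mice would lower Pck1, G6pc, Ppargc1a, Igfbp1 and Tat along with PPAR-alpha targets. The median log2 ratio of these 5 genes was 0.098, above −0.41 by slightly more than the SD of 0.48 among them. Igfbp1 was at 1.08 and G6pc at 0.27, while Pck1 (−0.065) and Ppargc1a (−0.046) were below 0. As a set these genes were not lower, but the SD among genes does not measure the spread between pools, so a fed state stays open. A shift of clock phase cannot be told apart from the treatment, because the difference of 0.29 between the Arntl and Nr1d1 groups of clock genes lay between the bounds set. In the Nr1d1 group, Nr1d1 was at −1.32, Per1 at −0.46, Nr1d2 at −0.29 and Hlf at −0.20, but Tef at 0.058. In the Arntl group, Npas2 was at 0.36 and Arntl at 0.15, but Cry1 at −0.0027, Nfil3 at −0.16 and Clock at −0.23. OTD itself, and differences between mice or pools, stay open and untested with 1 library per group.

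Most Mup genes were lower in the OTD pool and Mup19 was higher. The summed level of the 17 numbered Mup genes was 0.517 times control. That argues against reads moved among these genes as the whole cause of the lower copies. Mup pseudogenes and copies under other names were not in the sum. How reads matching several copies were counted is not given in the sources used here. Reads moved to copies outside the sum, or lost, therefore stay open. For Mup19, 100% of its 50-base stretches occur in other Mup transcripts, against 13.3% for Mup3, so its reads may come from another copy. Mup3, chosen after its value was seen, had a ratio of 0.848, so the size of the difference in single copies stays open, as does an effect of OTD.

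Ribosomal protein genes were lower by a small amount. Other protein-coding genes of the same length range with a mean of at least 100 (619 genes) had a median log2 ratio of −0.057, between the bounds set, so a part of the shift may come from length and abundance. The list still stood apart, with a median of −0.13, once a trend on annotated length, GC content and abundance was removed. That argues against this trend as the whole cause. Length was that of the longest annotated transcript, which may not be the expressed one. The length range compared ran from 493 to 3057 bases. A bias on the length of the expressed transcripts was therefore not isolated and stays open. An effect of OTD stays open and untested.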
